A study of Danio rerio with 6 samples.

How the data were processed

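Expression was measured with Affymetrix zebrafish arrays in total RNA from whole embryos of 72 h after fertilization. Per the labels' protocols, eggs pooled from several aquaria were injected with 50 uM morpholino up to the 4-cell stage and raised at 28 °C, and RNA was isolated from embryos kept in a stabilizing solution and labelled with biotin by in vitro transcription. The groups are ERbeta2 MO, coMO and uninjected, with 2 arrays each. Replicates are titled biological, but nothing says whether they came from separate spawnings, so p-values measure the spread between these samples. The number of arrays limits the precision, and with groups of 2 no test of single outlying arrays was made.

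The values analysed are the probe set intensities of the deposited value table, on a linear scale; they were made with MAS5 per the submitters' processing notes, and its version and settings are not given in the sources used here. The mean intensity after trimming 2% at each end is about 500 on every deposited array, which shows that the authors' values are scaled per array. A further 3 deposited tables hold the authors' fold, a linear ratio between groups, for 2723 probe sets of ERbeta2 MO over uninjected, 2666 of ERbeta2 MO over coMO and 21 of uninjected over coMO. Per the file headers these are fold change values, and none lies between 0.5 and 2; how the fold was computed and which other criteria applied are not given in the sources used here. Their directions were checked against the signals: 2714 of 2716, 2651 of 2652 and 21 of 21 probe sets without controls had the same sign. 1 identifier of the second table had no row in the value table. Detection calls were not used here, and columns of values with no sample numbered 0.

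Gene names came from these tables, which name 2326 of their 3139 probe sets with 1 gene, 219 with several and 594 with none; probe sets outside them are unnamed here. Symbols were updated through a reference gene table, by Entrez identifier for 1668 probe sets, by symbol for 41 and by older symbol for 197, and the file's symbol was kept for 420. An informative symbol was thus given to 1826 probe sets of 1670 genes. Because a probe set enters the tables only at a 2-fold difference, the named genes are selected on these samples. Of 118 genes with over 1 tested probe set, calr, igf2bp1 and papola had probe sets that changed in opposite directions between ERbeta2 MO and coMO, and each probe set keeps its own value.

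From the intensities, log2(signal + 16) was taken with no further normalization. The 115 control probe sets and the 40% of the others with the lowest mean over all arrays were left out, which left 9302. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on all 6 arrays with 3 residual degrees of freedom. To these eBayes adds a prior spread drawn from all probe sets, so limma's p-values rest on pooled spread as well as on replicates. Probe sets were called at a Benjamini-Hochberg adjusted p of 0.05. No replicate block was in the model.

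Of 31 gene lists fixed before the data were examined (sense organs, retina, lens, nervous system, muscle, blood, liver, gut and other tissues, and signalling, stress, clock and metabolic pathways), the 23 with at least 5 measured genes were tested. limma's camera was used with an inter-gene correlation of 0.01, against 1736 named genes with 1 probe set each (that with the highest mean). The p was adjusted over the 23 lists. An estimated correlation was tried for every list. With that option camera tests on only the 3 residual degrees of freedom, so only strong shifts can pass. A list that misses there is not shown to be undone by correlation between genes. Ribosomal protein genes, another of the lists, had 0 named members. limma's fry, an alternative, tests whether a list moves on balance one way and does not compare it with other genes.

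Genes were named by a rule fixed before the data were examined. Among tested probe sets with 1 informative symbol, past the threshold and with no overlap between the groups, the 12 largest increases and 12 largest decreases of each comparison were taken. To these came up to 4 members of each list by smallest p, a short set that took in receptor and neural genes, and the 5 named genes with the largest fold each way in each deposited table. Members outside the rule, named where a count was 5 or fewer or where a direction turned, were chosen after their values were seen. 1 gene of the short set, and the 1 tested list that holds it, are not reported here; the list stays in the adjustment and in the counts of lists.

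The fits were tested on simulated data: 200 of 9302 probe sets were changed by known folds, on the spread of the real arrays. For each of the 3 comparisons 52.2% of 67 changes of 1.5-fold, 95.5% of 67 of 2-fold and 100% of 66 of 4-fold were recovered. Calls that had not been planted made up 7.82% for ERbeta2 MO against coMO, 5.71% for ERbeta2 MO against uninjected and 3.51% for coMO against uninjected. A list shifted by 1 on the log2 scale between ERbeta2 MO and coMO was the 1 list of 23 called, for the 21 photoreceptor genes. Only that list was shifted, whereas 5231 of 9302 probe sets changed between the real ERbeta2 MO and coMO arrays. The list check therefore does not show how reliable list calls are in the real comparison. There 0 lists passed with an estimated correlation, a strict test on 3 residual degrees of freedom.

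Alternatives fixed beforehand were an offset of 1 or 64, quantile normalization, median centring, no filter, a filter on the lowest 60%, no variance trend, fits on the 4 arrays compared, a replicate block, each array left out in turn, an adjusted p of 0.1, counting genes in place of probe sets, an estimated correlation, and fry. Scaling on the poly-A spikes (dap, lys, phe, thr) or on the hybridization controls (bioB, bioC, bioD, cre), a Fisher's exact test of list members, and an estimated correlation with no filter, were chosen after seeing the data. The estrogen receptor genes, the atonal gene and the cell cycle inhibitor gene named in the rule were not analysed here. Genome coordinates were not used here.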

Results

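Gene expression was measured in whole zebrafish embryos at 72 h after fertilization, on 6 Affymetrix arrays that fall into 3 groups of 2. ERbeta2 MO embryos had been injected with a morpholino, a synthetic antisense oligonucleotide, against the estrogen receptor ERbeta2. coMO embryos had been injected with a control morpholino at the same 50 uM, and uninjected embryos received none. Per the series title, the study asked about a role of ERbeta2 in the development of neuromasts, the sense organs of the lateral line. Each array held 15502 probe sets besides 115 controls, and the median signal lay between 198 and 228 on the 6 arrays. Replicate arrays correlated at r = 0.982 to 0.990 across probe sets, which are not independent replicates. The coMO arrays correlated with the uninjected arrays at 0.978 to 0.986, and the ERbeta2 MO arrays with both kinds of control at 0.799 to 0.813. The first principal component held 88.6% of the variance and separated the ERbeta2 MO arrays from the other 4.

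The targeted gene could not be checked. A morpholino that blocks translation leaves the mRNA in place, so an mRNA level would not test it, and esr1, esr2a, esr2b and gper1 were not analysed here, nor were cdkn1a and atoh1a.

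The RNA of the ERbeta2 MO arrays also differed on the arrays' own control probe sets. The ratio of signal at the 3' end to that at the 5' end of GAPDH, a measure of RNA integrity and labelling, was 2.15 ± 0.00652 (SD, n = 2) in ERbeta2 MO, 1.5 ± 0.233 (SD, n = 2) in coMO and 1.41 ± 0.0877 (SD, n = 2) in uninjected embryos. For the muscle actin acta1 it was 12.6 ± 1.4, 6.68 ± 1.35 and 7.72 ± 3.28 (SD, n = 2 each). For the dap spike, an RNA added from outside, it was 4.28 ± 0.584, 4.44 ± 0.470 and 4.65 ± 0.815 (SD, n = 2 each). The spikes were dimmer on the ERbeta2 MO arrays. The mean log2 signal of the poly-A spikes was 6.74 ± 0.191 in ERbeta2 MO, 7.68 ± 0.224 in coMO and 7.38 ± 0.210 in uninjected embryos, and that of the hybridization controls 11.09 ± 0.0894, 11.55 ± 0.00431 and 11.47 ± 0.187 (SD, n = 2 each).

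Compared with coMO embryos, ERbeta2 MO embryos had far lower signals for genes of differentiated retina and gut and higher signals for genes led by an embryonic globin and by matrix proteases. The green cone opsin opn1mw1 fell 296-fold, from 13182 ± 198 (SD, n = 2) in coMO to 29.4 ± 12.1 (SD, n = 2) in ERbeta2 MO, with 15720 ± 2251 (SD, n = 2) in uninjected embryos. The ultraviolet cone opsin opn1sw1 fell 231-fold, from 23640 ± 1548 to 86.5 ± 10.6 (SD, n = 2 each), and the rod opsin rho 67.0-fold, from 12475 ± 772 to 170 ± 6.59 (SD, n = 2 each). The embryonic beta globin hbbe3 rose 102-fold, from 32.5 ± 15.3 to 4806 ± 511 (SD, n = 2 each), and the matrix metalloproteinase mmp9 26.1-fold, from 138 ± 0.571 to 4001 ± 125 (SD, n = 2 each). These folds are on the log2(signal + 16) scale, which understates the change of genes with low signals. The sizes for opn1mw1 and hbbe3, whose lower signals lie near the offset of 16, depend on that offset.

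Of 9302 probe sets tested, 5231 (56.2%) passed an adjusted p of 0.05 in limma, 2740 higher and 2491 lower, and 5650 had an unadjusted p below it. A change of at least 2-fold was found for 732 that were higher and 928 that were lower, and one of at least 8-fold for 5 and 115. The split changed with the filter and with some scalings. It was 2794 higher and 3539 lower with no filter and 2632 and 2362 with quantile normalization, close to that as deposited. It was 3634 higher and 1928 lower with each array centred on its median, 4721 and 1090 with arrays scaled on the hybridization controls, and 6397 and 424 with arrays scaled on the poly-A spikes, which were added before labelling. The median log2 difference of all probe sets, 0.05 as deposited, became 0.21, 0.48 and 0.95 under the last 3 scalings, and changes below are relative to the deposited scaling.

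The 12 largest increases by fitted change also took in mmp13a, a collagenase (log2 3.51), timp2b, an inhibitor of metalloproteinases (3.50), slc4a1a, the anion exchanger of red blood cells (2.90), and odc1, the first enzyme of polyamine synthesis (2.73). With them were the transcription factors fosl2 (2.79), atf3 (2.57) and atf5b (2.48), the cytokine signalling inhibitor socs3b (2.63), gtpbp1 (2.66) and ccdc86 (2.48). The 12 largest decreases took in 8 genes of phototransduction, among them pde6ha (log2 -6.84), gnat2 (-6.74), arr3a (-6.72), gnb3b (-6.67) and opn1sw2 (-6.25), together with the complement gene c3a.6 (-7.21), the pancreatic proteases ela2 (-6.65) and ctrb.1 (-6.60) and the liver fatty acid binding protein fabp10a (-6.18). Their limma adjusted p ran from 2.77e-21 to 4.56e-10, and for each of the 24 both arrays of one group lay above both arrays of the other. All 24 kept their direction under the 4 other scalings. In ERbeta2 MO embryos opn1mw1, gnat2, gnb3b, ela2 and fabp10a had mean signals of 16.7 to 29.4, near the offset, so the sizes and the order of the falls depend on the offset.

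Gene lists fixed beforehand were set against the other named genes with limma's camera, 23 lists having at least 5 members measured. The names come from the authors' tables, which list probe sets that differ at least 2-fold on these same samples, so the counts of members are not independent evidence of direction. Members counted below are those named there and tested, a minority of each list, such as 21 of 75 photoreceptor genes. The other members are unnamed here or below the filter. In the photoreceptor list 20 of 21 members fell and 1, the nuclear receptor gene nr2e3 (log2 0.68), rose, with a median log2 of -4.84 (adjusted p = 1.54e-08, and adjusted p = 0.150 with an estimated correlation). All 14 members of the exocrine pancreas list fell, at a median of -5.13 (adjusted p = 1.98e-07, and adjusted p = 0.245 with an estimated correlation), among them the trypsin gene prss1 (7853 ± 120 to 233 ± 2.77, SD, n = 2 each). In the intestine list 16 of 17 members fell, at a median of -2.17 (adjusted p = 7.13e-06, and adjusted p = 0.245 with an estimated correlation). Its leading members were the ileal bile acid binding protein fabp6 (log2 -5.53), the chitinase chia.2 (-5.15) and the microvillus protein vil1 (-4.28), and the remaining one, fabp1b.1, stood at -0.31 and above 0 with the spike scalings.

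The liver, cartilage, neuronal and lens lists were lower as well. In the liver and plasma protein list 15 of 18 members fell, at a median of -1.45 (adjusted p = 0.00487), with the iron carrier transferrin, tfa, at -2.17, and igfbp1a, a growth factor binding protein (1068 ± 115 to 5301 ± 327, SD, n = 2 each), cp and cfb (0.82) rose. The members kng1 and ambp turned positive with the poly-A scaling. In the cartilage, bone and connective tissue list 15 of 19 fell, at a median of -1.21 (adjusted p = 0.0185), led by the cartilage matrix gene matn1 (13368 ± 1073 to 497 ± 53.8, SD, n = 2 each) and the collagen col10a1a (log2 -3.78), while fn1b (1.91), fn1a, prrx1a (1.38) and sox9b (1.11) rose. The collagen gene col9a2 turned positive with the poly-A scaling. In the neuronal and synaptic list 19 of 21 fell, at a median of -1.13 (adjusted p = 0.00221), with the GABA-synthesizing enzyme gad1b at -2.04 and the synaptic vesicle protein syt1a at -1.52, and the early neuronal genes neurod4 (1.33) and elavl3 (1.09) rose. The members kif5aa, snap25a, sncb and atp1a3b turned positive with the poly-A scaling. All 5 members of the lens list fell, at a median of -1.60 (adjusted p = 0.0350), led by crygmxl2 at -2.28. Each of these 4 lists had an adjusted p = 0.245 with an estimated correlation. With the poly-A scaling fewer falls passed, 8 in the liver, 6 in the cartilage, 6 in the neuronal and 3 in the lens list, while 3, 4, 2 and 0 members were higher as before. With it the calls of the cartilage (adjusted p = 0.0515), neuronal (0.0569) and lens (0.0890) lists ended. The fall of these 7 lists went with the raised 3' to 5' ratios of GAPDH and acta1 in the same arrays.

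The red blood cell list rose. All 7 tested genes of the 29 on the red blood cell and heme list rose, at a median of 1.32 (adjusted p = 0.0213, and adjusted p = 0.256 with an estimated correlation), including hbbe2 (2207 ± 65.4 to 5527 ± 265, SD, n = 2 each) and alas2, the first enzyme of heme synthesis in red cells (log2 1.44). The call ended with the lowest 60% of probe sets left out, at an adjusted p = 0.0656. The ubiquitin ligase gene mdm2 rose by a log2 of 1.45. These rises too went with the raised 3' to 5' ratios. Adjusted over the list alone, the counts of these 8 called lists were those given, save that all 17 intestine genes then counted as lower.

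**Figure D1:**
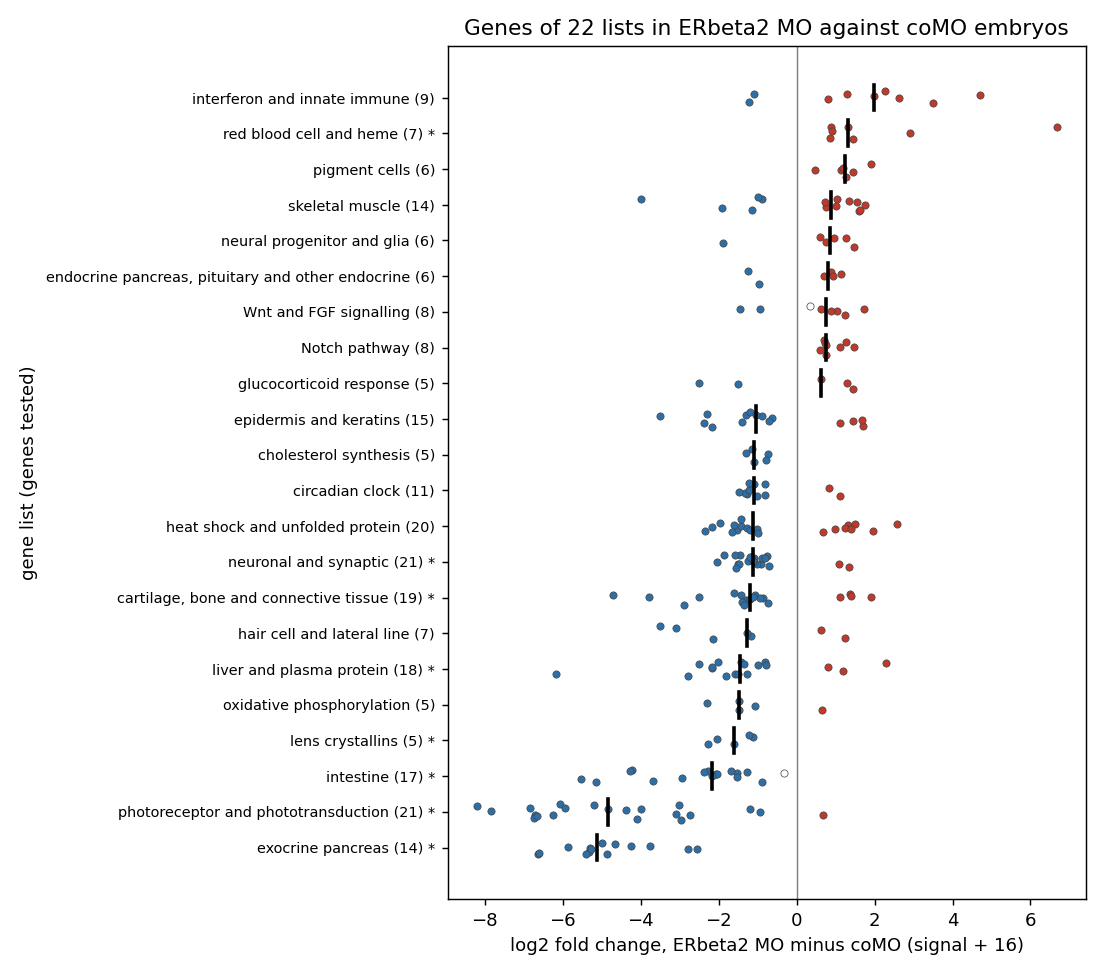
Log2 change between ERbeta2 MO and coMO embryos of the measured members of 22 gene lists, 1 point per gene, with a black bar at each list's median; red points passed the threshold as higher, blue points as lower, white points did not pass, and a star marks lists with an adjusted p under 0.05. Medians run from -5.13 (exocrine pancreas) to 2.00 (interferon and innate immune), and no list median changed sign under the 4 other scalings, though single members of 8 lists did with the poly-A spikes.

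The list of hair cell and lateral line genes, which stands closest to the study's question, did not pass (adjusted p = 0.118), at a median of -1.27. With no filter it had 10 members and a median of -0.26 (camera, adjusted p = 0.676), so its lean downwards depended on the filter. Of the 7 members past the filter 5 fell, among them krt15 (2748 ± 187 to 228 ± 38.0), the calcium binding proteins pvalb8 (2425 ± 134 to 268 ± 6.46) and calb2b (3688 ± 79.0 to 832 ± 108) and the synaptic protein otofa (380 ± 27.5 to 148 ± 6.06; SD, n = 2 each), and lef1 (log2 0.63) and fgf10a (1.25) rose. All 8 tested genes of the 56 on the Notch pathway list rose, at a median of 0.76, and the list missed the threshold (adjusted p = 0.0505). It passed in 5 of 17 alternative settings, among them no filter (camera, adjusted p = 0.0245). The ligands dla, dlb and jag1b stood at log2 1.27, 1.48 and 1.12 and the target her9 at 0.75. A probe set assigned to both notch3 and another locus rose by 0.59 (limma adjusted p = 0.00263), and one assigned to both neurog1, a neuronal determination gene, and another locus by 2.01 (9.35e-08).

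Of the other lists, the pigment cell list (median 1.23, 6 of 6 members higher, gch2 at log2 1.92) and the circadian list (median -1.10, 9 of 11 lower, per2 at -1.10, with cry2 at 0.82 and nfil3-5 at 1.12 higher) both had an adjusted p = 0.0505. Of 17 alternative settings the pigment cell list passed in 7 and the circadian list in 6. The interferon list below passed in 2 of 17 and cholesterol synthesis in 1 of 16. The circadian members fbxl3a and cry3a turned positive with the poly-A scaling. Cholesterol synthesis (5 of 5 lower, hmgcs1 at -1.29) stood at 0.0637, and its members acat2 and msmo1 turned positive with the poly-A scaling. The interferon and innate immune list, with mmp9, mmp13a, irg1l (2.26) and socs3b among 7 of 9 members higher and lyz (-1.23) and socs1a (-1.09) lower, stood at 0.0674. So did the epidermis list (11 of 15 lower, the keratin krt91 at -2.17, with anxa2a, krt18a.1, lye and cdh1 higher), where anxa1b, s100w and krt97 turned positive with the poly-A scaling. Oxidative phosphorylation (4 of 5 lower, ndufb2 at 0.64 higher) stood at 0.118. Neural progenitor and glia (5 of 6 higher, glula at -1.89 lower) and heat shock and unfolded protein (8 higher and 12 lower of 20, with the chaperone hsp90b1 at -2.36 and the stress transcription factor atf4a at 1.96) both stood at 0.270. Wnt and FGF signalling (5 of 8 higher, spry2 and sfrp1a lower, axin1 not past at 0.33) stood at 0.388. Skeletal muscle (9 higher and 5 lower of 14, ckmt2a at -3.99 and ttn.2 at 1.59) stood at 0.448; its member pvalb3 turned positive with the poly-A scaling. Endocrine genes (4 of 6 higher, ins at 0.94, neurod1 and ddc lower) stood at 0.669. The glucocorticoid list (3 of 5 higher, tat and pdk2b lower) stood at 0.964, with a median of 0.61 and a mean of -0.13. With the poly-A scaling the members that passed as lower numbered 1 of 11 in the circadian list, 0 of 5 in cholesterol synthesis (3 with the hybridization controls), 4 of 15 in the epidermis list, 3 of 7 in the hair cell list, 6 of 20 in the heat shock list, 2 of 14 in skeletal muscle and 1 of 5 in oxidative phosphorylation. In the interferon, endocrine and Wnt and FGF lists they numbered 0. Members named as exceptions to their list were picked after their values were seen.

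In the authors' deposited table for this comparison the folds of ERbeta2 MO over coMO were 249 for hbbe3, 46.0 for mmp9, 21.6 for the hatching enzyme gene he1.1, 20.8 for mmp13a and 18.8 for timp2b. The smallest in the authors' deposited table were 0.000874 for opn1mw1, 0.00164 for c3a.6, 0.00187 for opn1sw1, 0.00389 for gnat2 and 0.00408 for gnb3b. Of the 2117 probe sets of the authors' deposited table that were tested here, 2084 passed in the same direction.

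**Figure D2:**
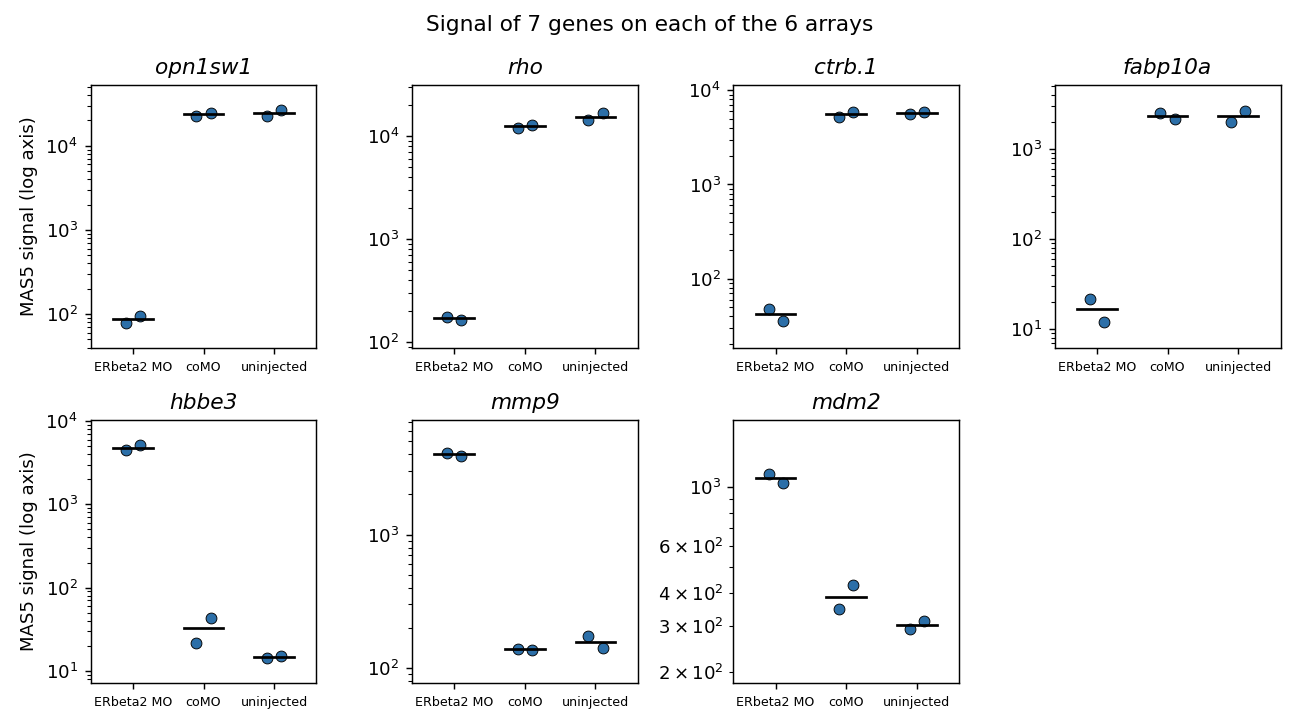
Deposited signal of 7 genes on each of the 6 arrays, on a log axis, 1 point per array with a line at the mean of each group of 2. The ERbeta2 MO arrays lie below all 4 control arrays for opn1sw1, rho, ctrb.1 and fabp10a and above them for hbbe3, mmp9 and mdm2, and these directions held under the 4 other scalings.

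The comparison with uninjected embryos holds the injection itself as well as the ERbeta2 morpholino. The largest falls of single genes were again those of cone opsins: opn1mw1 fell 351-fold from 15720 ± 2251 (SD, n = 2), and opn1sw1 by 7.90 on the log2 scale, from 24538 ± 2606 (SD, n = 2). hbbe3 rose from 14.7 ± 0.326 (SD, n = 2), which lies below the offset of 16, so the size of its rise depends on the offset. mmp9 rose 23.2-fold from 158 ± 22.4 and mmp13a 13.8-fold from 141 ± 26.2 (SD, n = 2 each). Genes among the 12 largest increases here and not against coMO were the complement gene c6.2 (log2 2.99), the membrane protein gene plppr1 (2.86) and the small heat shock protein gene hspb8 (2.81). Among the decreases pde6c, the catalytic subunit of cone phosphodiesterase (-6.47), was such a gene.

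limma found 5295 of 9302 probe sets past an adjusted p of 0.05, 2827 higher and 2468 lower, with 5743 below an unadjusted p of 0.05. The split was 2918 higher and 3239 lower with no filter, 2606 and 2333 with quantile normalization, 3531 and 1988 with median centring, 4296 and 1186 with the hybridization controls and 4939 and 627 with the poly-A spikes. 11 of the 23 lists passed. Photoreceptor (20 of 21 lower, median -4.81, adjusted p = 1.58e-08), exocrine pancreas (14 of 14 lower, -5.21, 2.42e-07), intestine (17 of 17 lower, -2.38, 6.07e-06), liver (15 of 18 lower, -1.79, 0.00324), neuronal (19 of 21 lower, -0.98, 0.00324), cartilage (15 of 19 lower, -1.22, 0.0186) and lens genes (5 of 5 lower, -1.43, 0.0462) fell. In these 7 lists only cyp1a, an intestine member, turned positive, with the poly-A scaling. Red blood cell genes (7 of 7 higher, 0.93, 0.0296) rose, as did Notch pathway genes (8 of 8 higher, 0.89, 0.0462), with dlb at 2.05 and dla at 1.61. Circadian genes were lower (9 of 11, -1.08, 0.0462), with the clock repressor gene nr1d2b at -1.59. Of the alternative settings the Notch list passed in 9 of 17 (adjusted p up to 0.118), the lens list in 11 of 16 (up to 0.177) and the circadian list in 12 of 17 (up to 0.254). With the poly-A scaling 11 liver, 10 cartilage, 7 neuronal, 3 lens and 4 circadian members still passed as lower. The neuronal and cartilage calls ended there (0.0979 and 0.0512), as did the lens, circadian and Notch calls. The red blood cell call ended with the lowest 60% left out (0.0802). None of the 11 passed with an estimated correlation: the photoreceptor list had an adjusted p = 0.150 with an estimated correlation, and the others lay up to 0.259. The names again come from tables chosen on these samples, the counts adjusted over the list alone were those given, and the 3' to 5' ratios were again higher in the arrays of the changed group.

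In the authors' deposited table of ERbeta2 MO over uninjected embryos the largest folds were 295 for hbbe3, 32.3 for mmp9, 25.9 for timp2b, 25.5 for mmp13a and 20.6 for he1.1. The smallest in the authors' deposited table were 0.000656 for opn1mw1, 0.00175 for opn1sw1, 0.0019 for c3a.6, 0.0033 for pde6c and 0.00338 for gnat2. Of 2149 probe sets of the authors' deposited table tested here, 2127 passed in the same direction.

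Both comparisons used the same 2 ERbeta2 MO arrays. Probe sets that passed in both numbered 2391 higher in both and 2160 lower in both, together 4551 or 87.0% of those changed against coMO, and 2 that changed in opposite directions. Independent lists of these sizes would share 833 higher and 661 lower, and 100 simulated sets of unchanged groups with shared arrays gave a mean of 0.01 and at most 1 probe set. Hardly any probe set can pass in groups without a difference, so that count does not show how much agreement the shared arrays add. Across probe sets the log2 changes correlated at 0.974, against 0.50 in the simulation, and their covariance was 0.832 against 0.0150. With 2 arrays the shared group could not be split, so part of the excess may come from the shared arrays. The shared probe sets were 4904 higher and 416 lower in both with the poly-A scaling. With the hybridization controls they were 4042 and 965.

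The comparison of coMO with uninjected embryos measures the control injection. Few genes differed, and none by 8-fold. hspb8 was 2.3-fold higher in coMO (225 ± 72.8 against 87.0 ± 14.7, SD, n = 2 each), and the lysosomal sorting gene vps33a, the cell adhesion gene alcama, scamp5a, plppr1 and the glucocorticoid-induced gene fkbp5 were higher by log2 0.96, 0.92, 0.90, 0.74 and 0.68. The lamin gene lmnb2 was 2.23-fold lower (373 ± 76.6 against 844 ± 82.9, SD, n = 2 each) and fosab, an immediate early transcription factor gene, 1.99-fold lower (706 ± 14.6 against 1427 ± 126, SD, n = 2 each). ppargc1b (-1.13), cfp (-1.04), diabloa (-1.03), midn (-0.87), irg1l (-0.85), tcima (-0.72) and fabp1b.1 (-0.72) were lower too. Both arrays of one group lay above both of the other for each of these 15 genes, and limma's adjusted p lay between 0.00128 and 0.0341. Of the 15, 11 no longer passed without coMO replicate 2, and fosab alone passed in every alternative setting.

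In this comparison 47 probe sets passed, 27 higher and 20 lower in coMO, and 734 had an unadjusted p below 0.05. The count was 10 to 41 with single arrays left out, 11 with no variance trend and 92, 51 higher and 41 lower, with a replicate block. It was 13, 1 higher and 12 lower, with the poly-A scaling and 16, 4 higher and 12 lower, with the hybridization controls, where the median of all probe sets moved from 0.00 to -0.28 and -0.07. 1 list passed, photoreceptor genes, with a median log2 of -0.24 (adjusted p = 0.00897, and adjusted p = 0.674 with an estimated correlation), though 0 of its 21 members passed singly and, adjusted over the list alone, 1 was higher and 2 lower. Among its members with the smallest p were rpe65a, of the visual cycle (-0.50), the rod transducin gene gnat1 (-0.48), pde6c (-0.53) and nr2e3 (0.65). The call ended without coMO replicate 1 (adjusted p = 0.186), without uninjected replicate 1 and without uninjected replicate 2. Of the other lists that changed against coMO in ERbeta2 MO embryos, the lens list had a median of 0.25 (adjusted p = 0.0946) with 0 of 5 members past the threshold, and passed as higher in 3 of 16 alternative settings. The medians were -0.04 (exocrine pancreas), -0.09 (intestine), -0.04 (red blood cell), -0.09 (liver), 0.10 (neuronal) and -0.01 (cartilage), with adjusted p of 0.943, 0.713, 0.943, 0.369, 0.405 and 0.943. Each of these medians but that of the liver list changed sign in some alternative setting, as did that of the lens list.

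The authors' deposited table for this pair lists 21 probe sets, 12 of the 15 tested here passing in the same direction. Its folds of uninjected over coMO were 3.04 for lmnb2, 2.67 for fosab, 2.44 for ppargc1b, 2.21 for irg1l and 2.15 for jdp2b, and 0.448 for plppr1, 0.465 for scamp5a and 0.479 for ncana, as the authors' deposited table gives them.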

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

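All tests in this part were chosen after the results were seen. On the ERbeta2 MO arrays the mean 3' to 5' ratio of GAPDH was 2.15, with the lower of the 2 arrays at 2.14 and the highest of the 4 control arrays at 1.66. The mean ratio of acta1 was 12.6, with 11.6 for the lower ERbeta2 MO array and 10.04 for the highest control array. These come from control probe sets outside the comparisons, and they stand above the level of every control array. Between ERbeta2 MO and coMO the 5' probe set of acta1 used in the ratio changed by log2 -1.66, and another 5' probe set of acta1 by -1.09. That of GAPDH changed by -1.53. The 3' probe sets fell too, at -0.74 for acta1 and -1.01 for GAPDH.

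The 52 photoreceptor, exocrine pancreas and intestine genes had a median log2 change of -4.24 between ERbeta2 MO and coMO, and the raised ratios make poorer RNA or weaker labelling of 5' ends a possible explanation. The dap spike was added before labelling, and its ratio was not raised. It was 4.28 ± 0.584 in ERbeta2 MO, 4.44 ± 0.470 in coMO and 4.65 ± 0.815 in uninjected embryos (SD, n = 2 each). For this 1 spike that argues against weaker labelling of 5' ends in general, and it does not bear on the embryos' own RNA. The largest fall of a 5' control probe set was -1.66, and 44 of the 52 genes fell by more. The 3 lists were picked for their fall, so that count was partly settled by the choice and does not exclude RNA quality. It shows falls larger than those of the 2 control genes. Under 4 other scalings the median nearest to 0 was -3.45, with the poly-A spikes. These scalings moved the median of all probe sets to at most 0.95. A scaling difference as large as the controls show would therefore not account for falls of this size. Loss of ERbeta2 protein stays open. That 96.2% of the genes (50 of 52) were lower against both control groups decides nothing, since the lists were picked for their fall and both comparisons share the ERbeta2 MO arrays. With 1 morpholino at 1 dose, and no rescue analysed here, it cannot be told apart from an off-target effect of the sequence, a general delay of development or a loss of these tissues.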

How the results depend on the processing

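The spike scalings, the Fisher's exact test and an estimated correlation with no filter were chosen after seeing the data; the other alternatives were not. For ERbeta2 MO, 18 of 19 alternatives gave counts within 1.5 times of 5231 against coMO and 5295 against uninjected embryos, and 18 of 18 did for the 4551 shared probe sets (3334 to 5320). The exceptions were 1678 and 1697 when genes were counted, since unnamed probe sets drop out; for coMO against uninjected embryos that count was 15. Leaving out single arrays gave 4126 to 5330, 4139 to 5403 and 3533 to 4116. A left-out array leaves its group with 1, which is assumed to vary like the others.

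The 47 probe sets of coMO against uninjected embryos became 21 with no filter, 11 with no trend, 13 with the poly-A and 16 with the hybridization scaling. They were 10 to 41 with single arrays left out: 16 without coMO replicate 1, 10 without coMO replicate 2 and 15 without uninjected replicate 2. The cause was not tested.

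Lists against coMO numbered 14 with no filter, where more genes were tested, and 22 with fry, 0 with an estimated correlation, with or without the filter, and 9 to 12 with single arrays left out, beside 9. Against uninjected embryos, beside 11, they were 7 with the lowest 60% left out, 6 with the poly-A and 7 with the hybridization scaling, 0 with an estimated correlation, with or without the filter, 22 with fry and 8 to 12 with single arrays left out. For coMO against uninjected embryos, beside 1, they were 2 with offset 64 or quantile normalization, 0 with an estimated correlation (with or without the filter), fry or the Fisher's exact test, and 0 to 1 with single arrays left out, 0 without coMO replicate 1, uninjected replicate 1 or uninjected replicate 2. The cause was not tested.

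Same-numbered arrays deviated together little (r = 0.0156, 0.0134 and 0.118). With a replicate block the counts were 5399, 5498 and 92, with 4736 shared, and 9, 8 and 2 lists.

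Of values of named genes, 1904 of 1930 against coMO, 454 of 455 against uninjected embryos and 256 of 318 for coMO against uninjected embryos kept direction and side of the threshold. Those that turned were acat2 against coMO, at 0.12 with the poly-A scaling, and 2 small differences of coMO from uninjected embryos. The neurog1 probe set was -0.14 with the poly-A scaling and -0.23 to 0.45 with single arrays left out, and the notch3 probe set -0.14 to 0.0518. The cause was not tested. Probe sets with low signals are limited by background, which the offset of 16 damps.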

Other observations

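All tests in this part were chosen after the results were seen. Genes of nucleolar ribosome assembly, which process ribosomal RNA and build ribosomal subunits, rose together in ERbeta2 MO embryos. The histone chaperone of the nucleolus npm1a went from 4068 ± 59.9 in coMO to 9766 ± 619, the snoRNP core gene nop58 from 810 ± 157 to 2443 ± 58.2 and nucleolin, ncl, from 3699 ± 446 to 7089 ± 316 (SD, n = 2 each). Of 82 named members 82 were higher, and for the 74 that had not prompted the idea the median log2 was 1.32 (camera p = 2.53e-11, adjusted p = 7.60e-11, and adjusted p = 0.0133 with an estimated correlation). This adjustment covered only the nucleolar, synthetase and immediate early gene lists of this part, not the 23 fixed lists. Before adjustment, camera with an estimated correlation gave p = 0.00443 here and p = 0.00652 for the fixed photoreceptor list, whose adjusted p was 0.150. The value of 0.0133 therefore does not show a firmer result than those of the fixed lists. Aminoacyl-tRNA synthetases, which load amino acids onto tRNA, rose likewise: 15 of 15 named members were higher, among them eprs1 (1940 ± 127 to 7081 ± 334) and rars1 (610 ± 53.2 to 2275 ± 91.9; SD, n = 2 each). The 13 that had not prompted the idea had a median of 1.31 (camera p = 0.000822, adjusted p = 0.00123, and adjusted p = 0.148 with an estimated correlation). These members too are named from tables chosen on these samples, and the 3' to 5' ratios were raised in the same arrays. Both groups may belong to a raised demand for protein synthesis or to an earlier developmental state; these were not tested. No member of either list changed sign between ERbeta2 MO and coMO under the 4 other scalings. In coMO against uninjected embryos the members that had not prompted the ideas ranked slightly higher too. Their medians were 0.0638 and 0.157 (camera, adjusted p = 0.0332 for both, and 0.135 and 0.222 with an estimated correlation). There 0 members passed singly, and with the poly-A scaling the medians of all members were -0.22 and -0.14.

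Lists with under 5 measured genes were not tested as lists. With no filter 1 of them, proliferation, had 7 measured genes and was called lower against coMO (median -1.29, limma's camera, adjusted p = 0.0271, and adjusted p = 0.165 with an estimated correlation) and against uninjected embryos (-1.42, limma's camera, adjusted p = 0.0316, and adjusted p = 0.188 with an estimated correlation). Their members, all past the threshold against coMO in limma, included the myelin genes mbpa (2191 ± 93.6 to 183 ± 12, SD, n = 2 each) and plp1b (log2 -2.61), while the oligodendrocyte lineage genes olig2 and nkx2.2a stood at 0.57 and 0.71. The sex hormone binding globulin gene shbg (533 ± 13.2 to 35.5 ± 10.3, SD, n = 2 each) and pdzk1 (log2 -2.17), both of the estrogen response list, were lower. Also lower were lyz of the leukocyte list (-1.23), the proliferation genes top2a (-1.29), dut (-0.97) and cdk2 (-0.92) and agr2 of the hatching gland list (-2.37). Higher were ctss2.1 of the leukocyte list (1.34), nppa (2.08) and ttn.2 (1.59) of the heart list and the vessel growth factor gene vegfaa (1.46). None of these 15 genes changed sign under the 4 other scalings, but lyz, top2a, dut and cdk2 no longer passed with the poly-A spikes, nor cdk2 with the hybridization controls. The hatching enzyme gene he1.1, below the filter and not tested, had signals of 912 ± 71.5 in ERbeta2 MO, 36.5 ± 40.4 in coMO and 19.6 ± 5.02 in uninjected embryos (SD, n = 2 each).

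The rise of fosl2, atf3, junbb and socs3b raised the hypothesis that AP-1 and immediate early genes rise as a group in ERbeta2 MO embryos. The other 11 members went both ways, with 5 of them higher and 5 lower, and egr1 and ier2b turned positive with the poly-A spikes. Their median log2 was 0.31 (limma's camera, adjusted p = 0.903). With 5 of the 11 lower, these members did not rise together under the deposited scaling. With members going both ways, the test does not decide whether the group rose on average. Whether only part of the group rises cannot be read from a median. Against uninjected embryos 4 were higher and 5 lower, with a median of -0.35, and fosab, higher against coMO, was not higher there (1279 ± 2.89 in ERbeta2 MO, 706 ± 14.6 in coMO and 1427 ± 126 in uninjected embryos, SD, n = 2 each). In coMO against uninjected embryos, fosab and jdp2b raised the hypothesis that such genes are lower after control injection. The 9 members that had prompted neither idea had a median log2 of -0.33 (camera p = 1.54e-05, adjusted p = 4.62e-05, and adjusted p = 0.0613 with an estimated correlation). The call thus ended with an estimated correlation. That option tests on only 3 residual degrees of freedom, so the lost call is not shown to come from correlation between genes. 0 of the 9 passed singly; ier2b stood at -0.57 and egr1 at -0.68. Such genes respond within minutes to handling, so a difference in how the dishes were collected could give the same values, and this was not tested.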
